A study of Bacillus subtilis subsp. subtilis str. 168 with 6 samples.

How the data were processed

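The deposited values are raw read counts per gene in each library, not normalised, and were used as the authors left them. Per the labels' protocols, RNA was stabilised in a protective reagent, purified on columns, depleted of ribosomal RNA and made into stranded total RNA libraries. Per the submitters' processing notes, reads went through Trimmomatic 0.36, FastQC 0.11.6, HISAT2 2.1.0 and SAMtools 1.6, and DESeq2 was used for the authors' own comparison, whose results are not used here. The program that counted the reads, its strand setting, the genome build and the annotation are not given in the sources used here. No coordinates are reported for that reason. Genes that overlap another gene, have an antisense partner or share near-identical copies are therefore uncertain, for example srfAB, inside which comS lies.

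Control 1 to 3 and MgCl2 1 to 3 are the unsupplemented and supplemented libraries under the numbers in their titles, which call them biological replicates. What a shared number means is not stated, so the numbers were not used to pair libraries. Each deposited table ends with 5 totals for reads given to no gene, which were kept apart from the genes. Of all reads, 76.6 to 77.8% were assigned to genes, 14.3 to 15.1% were ambiguous between genes, 3.44 to 3.70% fell on no feature, 3.81 to 4.67% had low quality, 0.341 to 0.713% were not aligned and 0.147 to 0.168% were not unique. The tables list 4544 features. The 252 rRNA and tRNA genes, with 0.0672 to 0.0922% of the reads, were left out before library sizes were taken.

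Locus tags linked 4371 features to RefSeq symbols, which differ from the symbols in the tables for 555. Genes are named as in the tables, with the RefSeq symbol beside some of them. Of the 681 members of the 36 gene lists, 661 were found by name, with efeB and efeN of the iron list leading to the same gene. The other 20 were not found, among them efeO, ltaS, citG and sdpC, and are not analysed as list members. Some of them may be in the tables under another symbol and so enter the tests over all genes. The lists, the tests and the alternatives were fixed before the data were examined.

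Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 3889. Counts were normalised by TMM and tested by edgeR's quasi-likelihood F-test with robust dispersion and Benjamini-Hochberg adjustment, at an adjusted p below 0.05. The SE of a log2 fold change is its absolute value over the square root of F. The common biological coefficient of variation was 11.3%. Gene lists with at least 3 tested members were compared with all other genes by camera on voom-weighted log2 CPM, with a preset correlation of 0.01, and camera p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A list's members were also adjusted over the list alone. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Similarity between libraries was measured on log2 CPM with a prior count of 2.

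Genes were named by a rule with 4 parts. The first took the 10 higher and 10 lower genes with the largest log2 fold change among those past the threshold, with at least 10 mean CPM in the higher group, no overlap between groups and at most 3 genes from a run of neighbours. The second was a fixed set of 15 genes for magnesium transport, division, cell shape, autolysins and motility (mgtE, citM, mpfA as yhdP, ftsZ, ftsA, ftsL, pbpB, minD, mreB, mreBH, lytE, cwlO, ugtP, hag and lytF). The third took up to 4 members with the smallest p from each list with a member past the threshold, and the fourth any member of a count of 5 or fewer. The rule gave 123 genes, and not all of those from the third part are printed.

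The alternatives were RLE size factors, DESeq2, no low-count filter, a stricter filter of 10 CPM in 3 libraries, rRNA and tRNA genes kept, a replicate block, dispersion without the robust option, and each library left out in turn. For a self-test, counts of the same size and spread were simulated with known changes. The 3889 simulated genes held 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, of which the tests recovered 62.7, 91.0 and 95.5%. Calls among unchanged genes numbered 18. Their share of all calls, which the adjusted p is meant to limit, is larger than their share of the 3889 genes. The self-test therefore does not show that false calls stayed within that limit. A simulated list of raised genes passed (camera adjusted p = 1.83e-18), and 0 random lists did. The simulated genes were drawn independently of each other, whereas the estimated correlation within real lists reached 0.82 (SigB). The random lists therefore do not show how often camera passes lists of correlated genes.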

Results

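Total RNA was sequenced from exponentially growing cultures of Bacillus subtilis 168, a rod-shaped Gram-positive laboratory strain. The cells grew in CH, a casein hydrolysate medium, with no added magnesium or with 10 mM MgCl2, and were collected at an optical density at 600 nm of about 0.2. Each group had 3 libraries from cultures labelled as separate biological replicates, named here control 1 to 3 (no supplement) and MgCl2 1 to 3. Reads assigned to genes numbered 18.87 M, 16.08 M and 19.25 M in control 1, 2 and 3, and 19.92 M, 21.08 M and 18.39 M in MgCl2 1, 2 and 3. Expression is given as normalised counts scaled to library size (CPM) as mean ± SD (n = 3 per group), and log2 fold changes (MgCl2 minus no supplement) as estimate ± SE. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes unless stated otherwise.

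The first principal component of log2 CPM held 64.8% of the variance and separated the 3 supplemented from the 3 unsupplemented libraries. Pearson correlations across genes were 0.993 to 0.997 within groups and 0.979 to 0.990 between groups; genes are not independent replicates, so these values describe similarity only. Replicates of a group differed by more than sampling noise in every pair, with chi-square values per degree of freedom of 12.7 to 63.6, so no library was a second sequencing run of another. Separate preparations from one culture are not excluded by this. Reads that aligned nowhere made up 0.528 ± 0.162% of each supplemented library and 0.368 ± 0.0264% of each unsupplemented one.

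The single comparison of the design asks how growth with 10 mM MgCl2 alters the transcriptome of wild-type cells, in a study concerned with how magnesium affects the frequency of cell division. Among the genes that rose most with MgCl2 were many of iron acquisition. The dhbB and dhbF genes of bacillibactin siderophore synthesis, the flavodoxin operon genes ykuN, ykuO and ykuP, and feuA, which encodes the binding protein for iron-loaded bacillibactin, rose by 2.69 to 3.23 on the log2 scale. The transcript that fell most was copB, named cadA in RefSeq, which encodes a metal-exporting ATPase. It fell from 124.5 ± 4.37 to 30.6 ± 1.44 CPM, a log2 change of -2.02 ± 0.06 (edgeR adjusted p = 4.81e-06). The genes wapA, for a secreted toxin of the cell wall, and wprA, for a cell wall-associated protease, fell by 1.23 ± 0.05 and 0.89 ± 0.04 (edgeR adjusted p = 1.4e-05 and 5.66e-05).

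Of 3889 genes tested, 285 changed at an adjusted p below 0.05, 154 of them higher and 131 lower with MgCl2. Higher genes moved further, with a median fold of 1.94 against 1.36 among lower genes. A change of at least 2-fold was reached by 76 genes, of which 71 were higher. The 5 that fell at least 2-fold were copB, wapA, its neighbour yxxG (wapI, the WapA immunity gene; -1.09), yxiF (-1.11) and yxzC (-1.14). Every library of one group lay above every library of the other for 29.4% of the tested genes, where chance gives 10%. The number of changed genes was 132, 89 and 108 without control 1, control 2 and MgCl2 2, and DESeq2 called 513. In the order control 1, control 2 and MgCl2 2 left out, higher genes numbered 77, 46 and 60, lower genes 55, 43 and 48, and genes changed at least 2-fold 48, 34 and 49. Lower genes also numbered 208 without control 3 and 82 without MgCl2 3.

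**Figure D1:**
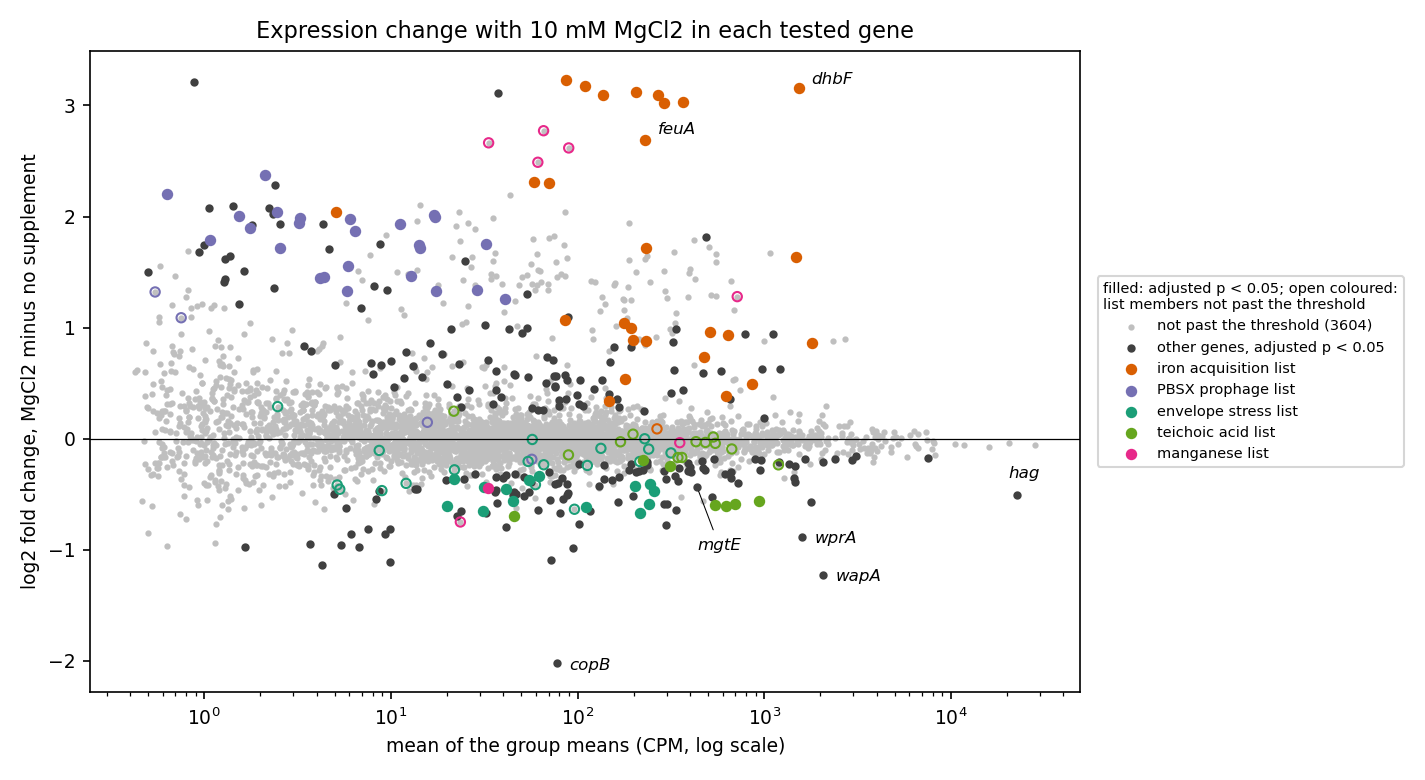
Log2 fold change (MgCl2 minus no supplement) against the mean of the group means in CPM on a log axis, 1 dot per tested gene. Filled coloured dots are list members with an adjusted p below 0.05 and open coloured circles are list members above it; all 28 iron acquisition genes and 28 of 29 PBSX genes lie above 0, most envelope stress genes below 0, and copB stands lowest at -2.02.

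The named genes of each direction are the 10 with the largest change at a mean of at least 10 CPM in the higher group, with at most 3 from a run of neighbouring genes. Low or neighbouring genes such as youA (3.21), dhbA (3.10), xkdH (2.37), yxzC (-1.14) and czcD (-0.96) changed more than some of them. Of the 10 increased genes, 9 belong to siderophore synthesis, siderophore uptake or the ykuNOP operon, and the remaining one is the prophage gene xkdF. The genes were ykuN (3.23 ± 0.50), ykuP (3.18 ± 0.43), dhbF (3.15 ± 0.42), dhbB (3.12 ± 0.40), ybdZ (mbtH; 3.11 ± 0.46), ykuO (3.09 ± 0.44), feuA (2.69 ± 0.46), feuC (2.31 ± 0.40), feuB (2.30 ± 0.43) and xkdF (2.02 ± 0.15). Their edgeR adjusted p-values ran from 0.000665 for xkdF to 0.0499 for feuB. The highest in abundance was dhbF, which rose from 309.6 ± 26.2 to 2756 ± 1328 CPM. The 10 decreased genes under the same limits were copB, wapA, yxiF, yxxG, yczI (-0.98 ± 0.08), wprA, yrhH (-0.86 ± 0.18), yrdP (-0.82 ± 0.09), ypzJ (-0.80 ± 0.08) and sunA (-0.78 ± 0.16), the last encoding the antimicrobial peptide sublancin. The edgeR adjusted p of sunA was 0.0406 and rose to 0.055, 0.119, 0.111 and 0.159 without control 1, control 2, MgCl2 1 and MgCl2 2, and to 0.223 with a replicate block, and that of yrhH rose from 0.0247 to 0.101, 0.0555 and 0.108 without control 2, MgCl2 1 and MgCl2 2. The other 8 decreased genes and xkdF passed with any single library left out. The 9 iron genes lost their call without control 1, control 2, control 3 or MgCl2 2 (edgeR adjusted p of dhbF = 0.0841, 0.105, 0.0585 and 0.0759, with 0.0198 on all libraries), and the feu genes without MgCl2 3 too (0.0551 to 0.0923). With a replicate block the 9 iron genes did not pass (edgeR adjusted p = 0.108 for dhbB to 0.194 for feuB). Without the low-count filter feuA, feuB and feuC did not pass (edgeR adjusted p = 0.0515, 0.064 and 0.0515), nor did feuB with RLE size factors (0.05002).

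Of 28 tested iron acquisition genes, 27 rose and none fell, and the same numbers held when adjusted over the list alone. The list had a median log2 change of 1.35, the highest value being 3.23, and all 28 members lay above 0. The list passed camera, which compares its members with all other genes (adjusted p = 5.72e-24), with adjusted p = 0.286 with an estimated correlation. The hydroxamate siderophore importer gene fhuC doubled from 128.5 ± 5.09 to 256.8 ± 41.7 CPM (1.00 ± 0.12), yfiY, for a siderophore-binding protein, rose from 1279 ± 43.1 to 2325 ± 198 CPM (0.86 ± 0.07), and efeN (efeB in RefSeq), of the elemental iron uptake system, from 358.7 ± 9.77 to 595.5 ± 59.6 CPM (0.73 ± 0.07). The small gene fbpB, which takes part in iron sparing, rose by 2.04 ± 0.21. These 4 had edgeR adjusted p-values of 0.00424, 0.000665, 0.00162 and 0.0018. Relative to the mean of the control libraries, the list median was 1.11 in MgCl2 1, 1.4 in MgCl2 2 and 1.6 in MgCl2 3. The number of higher members was 13, 7, 13 and 9 without control 1, control 2, control 3 and MgCl2 2, and 7 with a replicate block, where dhbF, ykuN and feuA had edgeR adjusted p-values of 0.124, 0.143 and 0.169. The edgeR adjusted p of ykuN, 0.0292 with all libraries, was 0.115, 0.139, 0.0756 and 0.106 in those fits, and that of feuA, 0.0404 with all libraries, was 0.139, 0.166, 0.0869 and 0.132, with 0.0911 without MgCl2 3.

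In the zinc list of 9 tested genes, the exporter genes copB and czcD fell (czcD -0.96 ± 0.11, edgeR adjusted p = 0.00277), and znuA, for a zinc-binding uptake protein, rose slightly from 208.3 ± 8.18 to 247.1 ± 8.97 CPM (0.25 ± 0.05, edgeR adjusted p = 0.0321). When adjusted over the list alone, 4 genes were higher (znuA, folEB, rpsNB and rpmEB) and 2 lower. The zinc list had a median of 0.04 and did not pass camera (adjusted p = 0.986), except as lower on DESeq2's values (0.0107). In the manganese list of 8 tested genes, only the efflux gene yeaB (mneS) passed over all genes, falling by 0.45 ± 0.09 (edgeR adjusted p = 0.0214). The manganese importer genes had large but variable log2 differences of 2.62 ± 0.61 for mntA, 2.66 ± 0.68 for mntB, 2.77 ± 0.64 for mntC, 2.49 ± 0.61 for mntD and 1.28 ± 0.26 for mntH, with edgeR adjusted p-values of 0.0565 (mntH) to 0.102 (mntB). There were 5 higher (mntA, mntB, mntC, mntD and mntH) and 2 lower genes (yeaB and ydfM) when adjusted over the list alone. DESeq2 gave the same numbers over all genes. The list had a median of 1.88 and a camera adjusted p of 0.336. Its median relative to the controls was 0.83 in MgCl2 1, 2.14 in MgCl2 2 and 2.25 in MgCl2 3. Without MgCl2 1, 5 manganese genes were higher and 2 lower over all genes, and camera gave an adjusted p of 0.00418. The call of yeaB was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.0694, 0.101, 0.094 and 0.0592), and that of znuA without any one of control 1 to 3 and MgCl2 1 to 3 (0.087, 0.11, 0.0588, 0.0765, 0.101 and 0.0586).

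**Figure D2:**
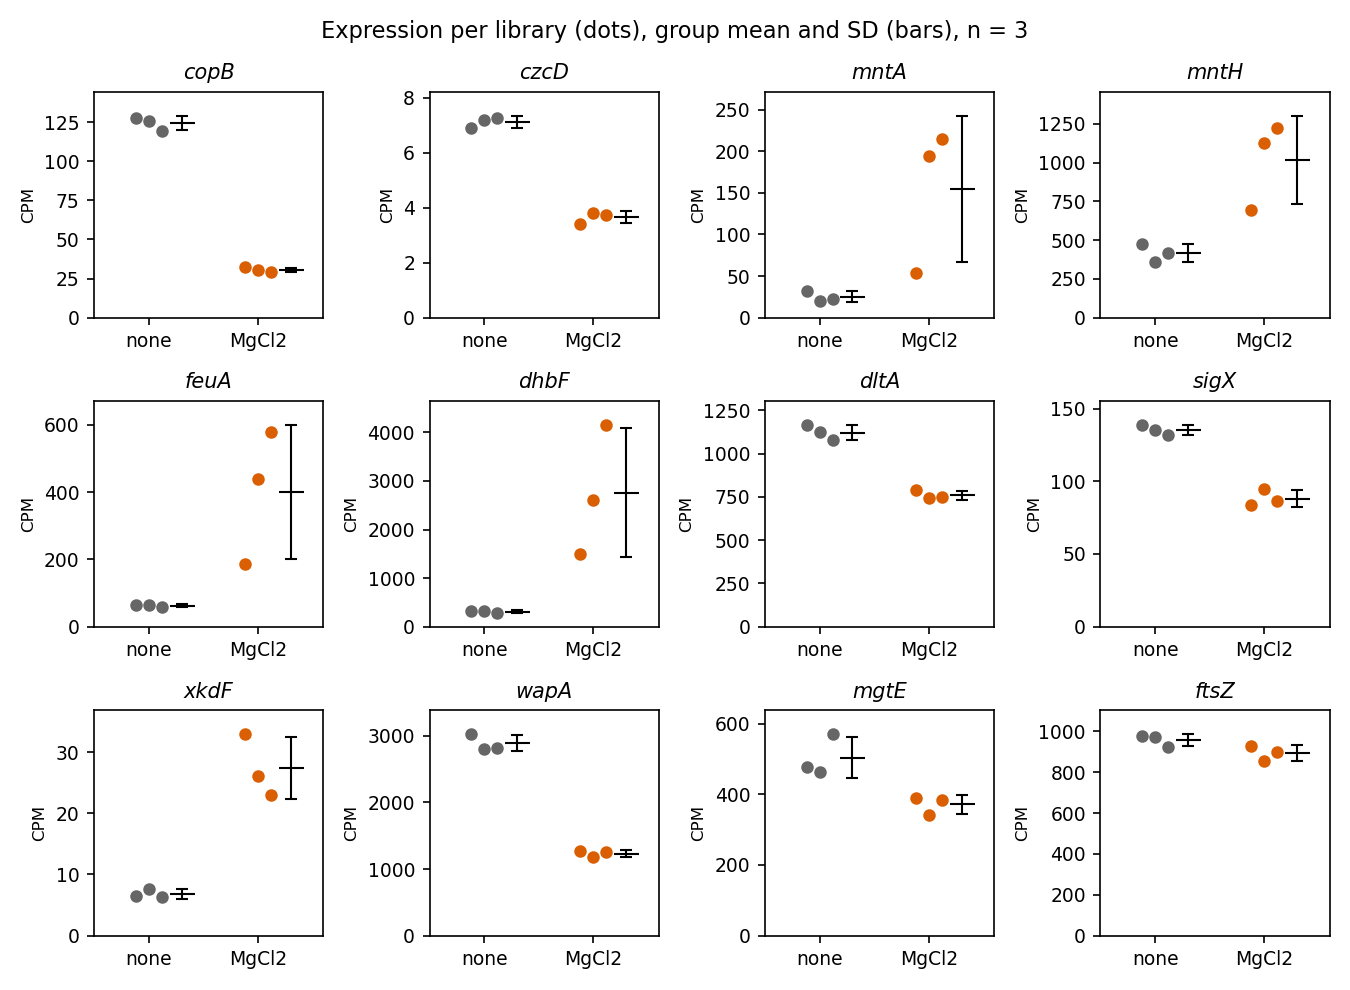
CPM of 12 genes in each library (dots), with the group mean and SD (black bars, n = 3 per group) and axes that start at 0. The metal exporter genes copB and czcD, and dltA, sigX and wapA, are lower with MgCl2 in every library, while mntA, feuA and dhbF are higher with a wide spread among the MgCl2 libraries.

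In the magnesium transport list of 7 tested genes, mgtE, the main magnesium importer, fell from 503.6 ± 58.1 to 371.2 ± 26.7 CPM (-0.44 ± 0.09, edgeR adjusted p = 0.0255). The citrate-magnesium transporter gene citM (0.22 ± 0.08) and yhdP, named mpfA in newer annotation and linked to magnesium efflux (0.15 ± 0.04), did not pass over all genes (edgeR adjusted p = 0.166 and 0.0823). The higher members were 2 (yhdP and yqhB) and the lower 1 (mgtE) when adjusted over the list alone. The list had a median of 0.12 and a camera adjusted p of 0.675. The mgtE call was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.057, 0.0541, 0.102 and 0.0623).

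Genes of the defective prophage PBSX rose together. Of 29 tested genes 25 rose, with 27 higher and 1 lower (xre, for the phage repressor, -0.19 ± 0.07) when adjusted over the list alone. The median was 1.74, and the list passed camera (adjusted p = 5.26e-19), with adjusted p = 0.328 with an estimated correlation. Levels were low. The genes xkdF, xkdE and xkdJ, for phage structural proteins or proteins near them, went from 6.78 ± 0.80 to 27.4 ± 5.04, from 6.67 ± 0.73 to 22.0 ± 4.18 and from 1.32 ± 0.16 to 5.22 ± 0.72 CPM, and xkdO from 24.2 ± 0.66 to 57.9 ± 10.7 CPM. Their edgeR adjusted p-values were 0.000665, 0.00092, 0.00092 and 0.00178. In the SOS list of 16 tested genes 2 fell and none rose, over all genes and adjusted over the list alone: lexA, for the SOS repressor, from 390.2 ± 15.7 to 298.3 ± 3.82 CPM (-0.39 ± 0.05, edgeR adjusted p = 0.00424), and dinB from 54.8 ± 1.98 to 38.7 ± 1.67 CPM (-0.50 ± 0.07, edgeR adjusted p = 0.00499). The SOS list had a median of -0.02 and a camera adjusted p of 0.471. PBSX genes called higher numbered 13 without control 2 and 10 under a stricter minimum of expression, which left 12 to test. The SOS list members uvrX (0.72 ± 0.23) and yneB (0.42 ± 0.13) did not pass (edgeR adjusted p = 0.109 and 0.0924), and 1 gene of that list was higher without MgCl2 1 and with a replicate block. The gene uvrX lies within another prophage, SPβ.

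Cell envelope stress genes fell. Of 32 tested genes controlled by the extracytoplasmic function sigma factors SigW, SigM and SigX, 14 fell and none rose, and 24 were lower when adjusted over the list alone. The median was -0.41 and the list passed camera (adjusted p = 6.13e-15), with adjusted p = 0.0869 with an estimated correlation. The sigma factor gene sigX fell from 135.1 ± 3.41 to 88.1 ± 5.71 CPM and its anti-sigma factor gene rsiX from 265.8 ± 8.22 to 166.9 ± 7.21 CPM, log2 changes of -0.62 ± 0.06 and -0.67 ± 0.05. The regulator gene abh fell by 0.59 ± 0.05 and the penicillin-binding protein gene pbpE by 0.56 ± 0.06. Their edgeR adjusted p-values were 0.00162, 0.000729, 0.000827 and 0.0018 in the order given. Among 19 tested teichoic acid genes 7 fell, with 10 lower and 1 higher (tagC, 0.25 ± 0.08) when adjusted over the list alone. Within it the operon for D-alanylation of teichoic acids fell as a block, with dltA at -0.56 ± 0.05 (1121 ± 42.5 to 759.1 ± 26.9 CPM), dltB at -0.60 ± 0.05, dltD at -0.59 ± 0.04 and dltE at -0.61 ± 0.05, all with edgeR adjusted p below 0.001. The teichoic acid list had a median of -0.17 and passed camera (adjusted p = 1.47e-06), with adjusted p = 0.169 with an estimated correlation. The envelope stress count was 8, 7 and 7 without control 1, control 2 and MgCl2 2, and the teichoic acid count 4 and 4 without control 1 and control 2. The 6 LiaRS genes, which respond to antibiotics acting on the lipid II cycle, had a median of 0.00 and a camera adjusted p of 0.889.

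The cell division genes showed small differences. Among 11 tested divisome genes ftsL, for a short-lived bitopic division protein, fell from 109.3 ± 2.55 to 93.3 ± 3.43 CPM (-0.23 ± 0.05, edgeR adjusted p = 0.0442). The other 10 did not pass over all genes, and pbpB, for the division transpeptidase, was lower too when adjusted over the list alone, which made 2. The tubulin homologue gene ftsZ was at 956.8 ± 30 and 895.1 ± 37.7 CPM (-0.10 ± 0.05), its membrane anchor gene ftsA at 729.1 ± 5.38 and 711.9 ± 17.9 CPM (-0.03 ± 0.04), and pbpB differed by -0.22 ± 0.06, with edgeR adjusted p-values of 0.282, 0.682 and 0.0739. The divisome list had a median of -0.06 and a camera adjusted p of 0.111. Among 9 tested genes of division site control, ugtP, for the glucosyltransferase that couples division to nutrients, fell from 448.9 ± 7.75 to 363.6 ± 13.8 CPM (-0.30 ± 0.05, edgeR adjusted p = 0.00928). Adjusted over the list alone 2 were lower, ugtP and minD (-0.15 ± 0.05, edgeR adjusted p = 0.0894 over all genes), and the camera adjusted p was 0.758. The ftsL call was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.174, 0.157, 0.161 and 0.114) and the ugtP call without control 2 (0.0595), while 1 division site gene was higher without control 3.

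In the list of 10 elongation and cell shape genes, rodA, for a cell wall polymerase of the elongasome, fell by 0.24 ± 0.06 (edgeR adjusted p = 0.0443), the only one also when adjusted over the list alone. The actin homologue genes mreB (-0.12 ± 0.04) and mreBH (-0.03 ± 0.14) did not pass (edgeR adjusted p = 0.135 and 0.921). The median was -0.10 and the list passed camera (adjusted p = 0.0208), with adjusted p = 0.345 with an estimated correlation. Among 20 tested peptidoglycan precursor genes 3 fell, over all genes and adjusted over the list alone. They were bcrC, for an undecaprenyl pyrophosphate phosphatase (197.5 ± 8.42 to 133.1 ± 4.47 CPM, -0.57 ± 0.06), ddl (-0.22 ± 0.05) and murAA (-0.19 ± 0.04), with edgeR adjusted p-values of 0.0013, 0.0253 and 0.0339. The median was -0.08 and the list passed camera (adjusted p = 0.0199), with adjusted p = 0.286 with an estimated correlation. The rodA call was lost without any one of control 1 to 3 and MgCl2 1 to 3 (edgeR adjusted p = 0.133, 0.104, 0.0606, 0.102, 0.113 and 0.0794), and the elongation list lost camera's threshold without MgCl2 3 (0.0769) and with DESeq2 (0.0698). Precursor genes called lower numbered 1 without each of control 1, control 2, MgCl2 2 and MgCl2 3, and bcrC was past the threshold in every fit. The gene ddl also lost its call without MgCl2 1 (0.0563).

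Among 14 tested autolysin genes 3 rose and 1 fell, and 5 were higher (iseA, lytA, lytB, lytC and pdaC) and 1 lower (lytF) when adjusted over the list alone. The gene iseA, for an inhibitor of autolysins, rose from 29.0 ± 4.69 to 57.2 ± 11.9 CPM (0.98 ± 0.18), and lytA and lytB, which lie upstream of the amidase gene lytC, rose by 0.40 ± 0.07 and 0.35 ± 0.07. The endopeptidase gene lytF fell from 684.5 ± 52.7 to 549.1 ± 33.4 CPM (-0.32 ± 0.07). The edgeR adjusted p-values were 0.0248, 0.0152, 0.0194 and 0.0338. The endopeptidase genes lytE (0.00 ± 0.10) and cwlO (-0.10 ± 0.06) did not pass (edgeR adjusted p = 0.991 and 0.419). The list had a median of 0.01 and a camera adjusted p of 0.449. Higher members numbered 2, 1, 2 and 0 without control 1, control 2, control 3 and MgCl2 2 (edgeR adjusted p of iseA = 0.087 without control 1, 0.0759 without control 3, 0.105 without MgCl2 2 and 0.0631 with a replicate block, and of lytA and lytB = 0.0664 and 0.0887 without control 2 and 0.0596 and 0.0801 without MgCl2 2). There were 2 lower members without control 3, and the lytF call was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.126, 0.135, 0.0997 and 0.0877).

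The flagellin gene hag, among the most abundant transcripts, fell from 26576 ± 3205 to 18692 ± 1845 CPM (-0.51 ± 0.11, edgeR adjusted p = 0.0439). It was the 1 gene of 46 in the flagella and chemotaxis list to pass, and 0 passed when adjusted over the list alone, while 12 genes had an unadjusted edgeR p below 0.05 and DESeq2 called 5 over all genes. The list had a median of -0.15 with 4 members above 0 and passed camera (adjusted p = 1.18e-05), with adjusted p = 0.735 with an estimated correlation. The hag call was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.0863, 0.17, 0.17 and 0.12), and 7 genes of the list were lower without control 3 and 9 with a replicate block. Library medians of the list overlapped between groups, at 0.11, -0.02 and -0.11 in control 1, 2 and 3 and -0.09, -0.16 and -0.23 in MgCl2 1, 2 and 3, and the list median was -0.09 without control 1 and -0.23 without control 3. In the biofilm matrix list of 23 genes only slrA, for a small regulator of matrix genes, passed, over all genes and over the list alone (-0.36 ± 0.07, edgeR adjusted p = 0.0197), and camera gave an adjusted p of 0.431 with a median of 0.07. The slrA call was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.0861, 0.0999, 0.0872 and 0.0654).

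Among 17 tested genes for surfactin and cannibalism toxins, srfAA, the first gene of the surfactin synthetase operon, rose from 215.8 ± 7.10 to 757.7 ± 265 CPM (1.81 ± 0.28, edgeR adjusted p = 0.0292). Adjusted over the list alone 4 were higher, srfAA, srfAB (1.5 ± 0.31), srfAC (1.37 ± 0.27) and srfAD (1.38 ± 0.29). The median was 0.15 and the list passed camera (adjusted p = 0.0215), with adjusted p = 0.286 with an estimated correlation. The srfAA call was lost without control 1, control 2, control 3 and MgCl2 3 (edgeR adjusted p = 0.111, 0.138, 0.0718 and 0.0915), the list's camera call was lost without MgCl2 3 (0.0662), and 4 genes were higher without MgCl2 2, by DESeq2, with the stricter filter and without robust dispersion. With a replicate block srfAA had an edgeR adjusted p of 0.101. The list median was 0.10 without control 2, and 0.77 with the stricter filter, which left 8 genes.

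General stress genes controlled by SigB were higher in the supplemented group as a list, with a median of 1.36 and all 22 members above 0, but no single gene passed. The edgeR test called 0 members over all genes and 0 adjusted over the list alone, 18 had an unadjusted p below 0.05, and DESeq2 called 15. The list passed camera (adjusted p = 7.06e-12), with adjusted p = 0.447 with an estimated correlation. The control libraries themselves were far apart, with list medians of -0.67, 0.02 and 0.56 relative to their own mean in control 1, 2 and 3, against 1.86, 1.16 and 1.19 in MgCl2 1, 2 and 3. Called members numbered 3 without control 3, 1 without MgCl2 3 and 7 without robust dispersion. In the heat shock list of 16 genes, 3 rose, over all genes and adjusted over the list alone. These were ctsR (1.10 ± 0.14), mcsA (0.95 ± 0.15) and mcsB (0.83 ± 0.15) of the clpC operon, with edgeR adjusted p-values of 0.00708, 0.0109 and 0.0235. The heat shock median was 0.08 and the list passed camera (adjusted p = 0.0208), with adjusted p = 0.735 with an estimated correlation. Without control 2 none of these 3 passed (edgeR adjusted p = 0.0528, 0.0611 and 0.111 for ctsR, mcsA and mcsB), without MgCl2 2 mcsA and mcsB did not (0.0576 and 0.0939), without MgCl2 1 mcsB did not (0.0676), with a replicate block none did (0.108, 0.103 and 0.168), and camera's adjusted p was 0.102 and 0.0662 without control 1 and MgCl2 3. Heat shock medians by library overlapped between groups (-0.08, -0.01 and 0.10 in control 1, 2 and 3; 0.02, 0.09 and 0.12 in MgCl2 1, 2 and 3), and the list median was 0.05 without either control 1 or MgCl2 2.

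Among metabolic lists, that of gluconeogenesis and the tricarboxylic acid cycle was lower, with 7 lower of 14 tested and 9 lower when adjusted over the list alone. These 9 were genes of the tricarboxylic acid cycle (citZ, citB, icd, odhB, sucD, sdhA, sdhB, sdhC and mdh). The gluconeogenesis genes pckA and gapB were not among them. The aconitase gene citB fell from 2129 ± 37.2 to 1434 ± 193 CPM (-0.57 ± 0.09), the citrate synthase gene citZ from 1664 ± 8.79 to 1267 ± 151 CPM (-0.39 ± 0.08), and the succinate dehydrogenase genes sdhC and sdhB by 0.29 ± 0.04 and 0.21 ± 0.04. The edgeR adjusted p-values were 0.0132, 0.0234, 0.00784 and 0.0214. The median was -0.15, no member lay above 0, and the list passed camera (adjusted p = 7.34e-07), with adjusted p = 0.169 with an estimated correlation. The count was 2, 0, 1 and 3 without control 1, control 2, MgCl2 2 and MgCl2 3, where citB had an edgeR adjusted p of 0.0611 without control 2 and 0.0687 without MgCl2 2. The citZ call was lost without control 1, control 2 and MgCl2 2 (edgeR adjusted p = 0.0824, 0.0978 and 0.108). That of sdhC was lost without control 2 (0.0528), and that of sdhB without control 1, control 2, MgCl2 2 and MgCl2 3 (0.0893, 0.104, 0.0868 and 0.0682). Among 23 tested genes of the osmotic and potassium response 2 fell, over all genes and over the list alone, the potassium importer gene ydaO (kimA; -0.28 ± 0.05) and the glycine betaine importer gene opuAA (-0.19 ± 0.04), with edgeR adjusted p-values of 0.0186 and 0.0417. That list had a median of -0.11 and passed camera (adjusted p = 0.0215), with adjusted p = 0.286 with an estimated correlation. Its camera call was lost without control 3 and MgCl2 1 (0.128 and 0.0561), with DESeq2 (0.0721) and with the stricter filter (0.103). Its count was 0 without control 2, MgCl2 2 and MgCl2 3, and 1 without control 1, without MgCl2 1 and with a replicate block.

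Among 51 tested ribosomal protein genes, rpmC rose (0.31 ± 0.06) and rpsD fell (-0.17 ± 0.04), over all genes and adjusted over the list alone, with edgeR adjusted p-values of 0.0197 and 0.0266. The list had a median of -0.01 and a camera adjusted p of 0.471. The rpmC call was lost without control 1, control 2 and MgCl2 2 (edgeR adjusted p = 0.0828, 0.102 and 0.0765) and the rpsD call without those and MgCl2 3 (0.124, 0.12, 0.0752 and 0.0675), while 7 genes were lower without control 3 and 2 without MgCl2 1. In the sulfur list of 14 tested genes, ssuC, for a sulfonate transporter, rose by 1.5 ± 0.35 at a level below 1 CPM (edgeR adjusted p = 0.0424). Adjusted over the list alone 2 were higher (ssuC and ssuD) and 2 lower (cysH and metA), with a list median of -0.09 and a camera adjusted p of 0.687. Without the low-count filter 20 sulfur genes were tested, with a median of 0.22 and a camera adjusted p of 0.853. The ssuC call was lost without any one of control 1 to 3 and MgCl2 1 to 3 (edgeR adjusted p = 0.133, 0.111, 0.0838, 0.0645, 0.148 and 0.0917) and with a replicate block (0.0829), where 3 sulfur genes were lower. In the respiration list of 23 tested genes, nasF, of nitrite reduction, fell by 0.49 ± 0.12 (edgeR adjusted p = 0.0433), and 0 passed when adjusted over the list alone, while 1 had an unadjusted edgeR p below 0.05 and DESeq2 called 1 over all genes. The respiration median was 0.02 and the camera adjusted p 0.946, and the nasF call was lost without control 1, control 2, MgCl2 2 and MgCl2 3 (edgeR adjusted p = 0.144, 0.159, 0.159 and 0.119).

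No member of 14 lists with 192 tested genes passed the edgeR test over all genes. Of these genes 39, of them 18 SigB genes, had an unadjusted edgeR p below 0.05. That is a smaller share than the 890 of all 3889 tested genes. DESeq2 called 19 in these lists, of which 15 are the SigB genes described above. Apart from SigB and LiaRS, these were the phosphate starvation regulon PhoPR (15 tested, median 0.05, camera adjusted p = 0.946), early sporulation (16, 0.06, 0.508), competence (13, 0.00, 0.986), the ATP synthase (9, 0.07, 0.152), glycolysis (9, 0.02, 0.986) and overflow metabolism and fermentation (12, -0.01, 0.986). The remaining ones, with the same values in the same order, were purine synthesis (16, -0.02, 0.864), pyrimidine synthesis (11, 0.14, 0.75), arginine synthesis and catabolism (12, -0.02, 0.449), branched-chain amino acids (10, 0.05, 0.986), histidine and peptide utilization (20, -0.03, 0.652), and fatty acid and phospholipid synthesis (21, -0.05, 0.111). With each list adjusted over the list alone, 1 competence gene was higher (comGG, 1.69 ± 0.42) and 1 lower (ssbB, -0.43 ± 0.11), 1 overflow gene was higher (acoB, 0.81 ± 0.20), and 0 passed in the other lists. Fatty acid genes passed camera as lower without control 3 and MgCl2 2 (adjusted p = 0.0319 and 0.00468). With 1 library left out, genes called in these lists were 1 in early sporulation, 1 in competence and 3 in fatty acid synthesis without control 3, 1 each in competence, the ATP synthase and pyrimidine synthesis without MgCl2 1, and 1 in overflow metabolism without MgCl2 2.

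Of the 36 lists, 12 passed camera with the preset correlation, 5 higher and 7 lower, and 0 passed with an estimated correlation, where 5 had an unadjusted camera p below 0.05. Correlation within the lists does not alone account for this loss. Peptidoglycan precursors and the osmotic list had estimated correlations of -0.03 and -0.0006, below the preset 0.01. Their unadjusted camera p still rose, from 0.00442 to 0.036 and from 0.00718 to 0.0412. Each of the 12 also passed in at least 1 of the 9 other splits of the libraries into 3 and 3, and flagella, SigB, heat shock, osmotic and elongation had a lower adjusted p in one of those than in the real split. Those splits mix both conditions unevenly and still hold part of the MgCl2 contrast, so a responding list can pass there. Such passes of a responding list do not measure false calls. Lists with no camera call in the real split passed there too, however. Among them, purine synthesis passed in 6 of the 9 (camera adjusted p down to 3.49e-12, against 0.864), sulfur in 4, and pyrimidine and fatty acid synthesis in 3 each. Part of the MgCl2 contrast does not readily account for those, so camera with the preset correlation may pass lists without it. DESeq2 called more members higher among autolysins (5), heat shock (4) and zinc genes (3), and 1 each in magnesium transport, division site control and the osmotic list. More were lower among envelope stress (19), teichoic acid (9), precursor (4) and osmotic genes (3). The same held for ribosomal proteins (4), the divisome (2), division site control (2), biofilm (2) and sulfur genes (2). PBSX genes called higher were 24 with DESeq2 and 25 with edgeR. By fry, which asks whether a list's genes move one way without comparing them with other genes, the adjusted p was 0.0139 for iron acquisition, 0.0188 for PBSX, 0.00102 for envelope stress, 0.00145 for teichoic acids, 0.00444 for gluconeogenesis and the tricarboxylic acid cycle, 0.0269 for elongation, 0.00444 for peptidoglycan precursors, 0.0255 for surfactin, 0.0667 for SigB, 0.255 for flagella, 0.143 for heat shock and 0.0505 for the osmotic and potassium response. Of the lists that did not pass camera, fry gave 0.000201 for zinc, 0.0269 for the divisome and 0.0269 for SOS, all lower, and 0.0269 for early sporulation, higher. The zinc genes did not fall as a set. Of 9 tested, 5 lay above 0, with a median of 0.04, while copB and czcD were at -2.02 and -0.96. In 9 lists the median, the mean and camera's direction differed in sign, all of them lists that did not pass: zinc, division site control, competence, glycolysis, overflow and fermentation, branched-chain amino acids, histidine and peptide utilization, sulfur, and respiration.

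**Figure D3:**
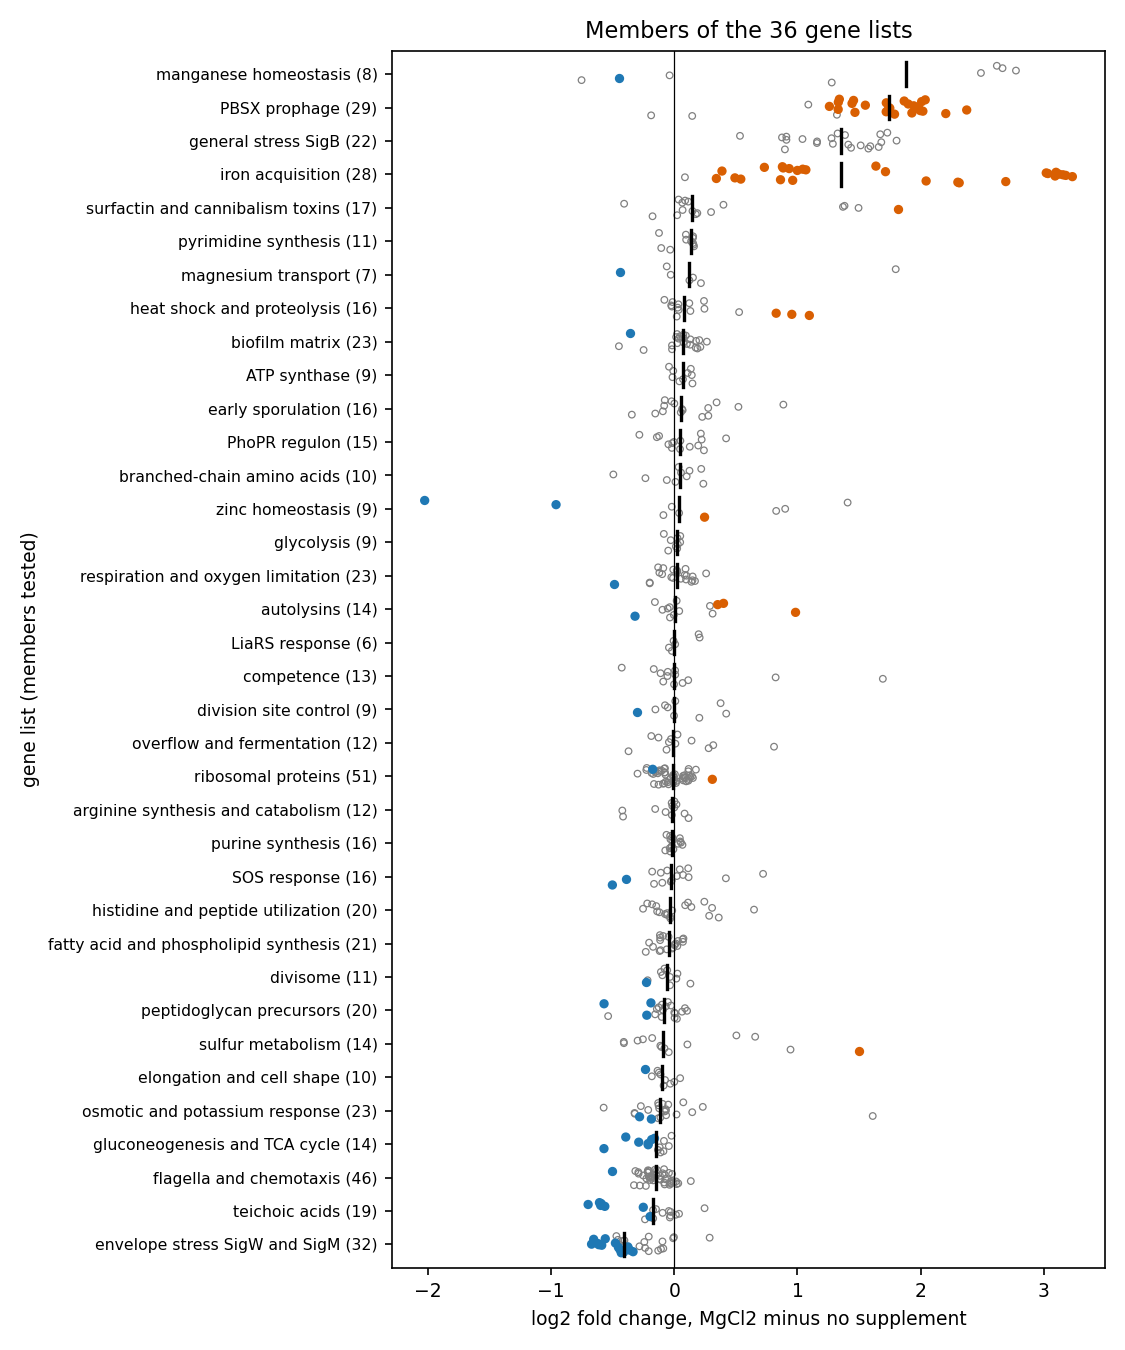
Log2 fold change (MgCl2 minus no supplement) of each tested member of the 36 gene lists, with the number tested in brackets and the list median as a black bar. Filled dots passed over all genes (orange higher, blue lower) and open circles did not; 27 of 28 iron acquisition genes and 25 of 29 PBSX genes are filled on the higher side and 14 of 32 envelope stress genes on the lower side.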

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

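The explanations weighed in this part and the tests set against them were chosen after the values were seen. The edgeR, DESeq2 and camera calls, the leave-one-out fits and the other alternatives they draw on were planned.

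Of 6 classes of reads outside the tested genes, 2 were higher in every supplemented library than in any unsupplemented one, and the ambiguous, no feature, low quality, and rRNA and tRNA reads overlapped between groups. Reads not aligned made up 0.528 ± 0.162% against 0.368 ± 0.0264%, and reads not aligned uniquely 0.161 ± 0.00683% against 0.151 ± 0.00362% (mean ± SD, n = 3 per group). The exact permutation p was 0.1 for both, two-sided, the smallest that 3 against 3 libraries can give. For reads not aligned uniquely the groups barely separated, with 0.154013% in MgCl2 3 and 0.1539% in control 3. The content of both classes of reads was not analysed here.

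Iron acquisition genes rose with MgCl2, with a list median of 1.35. Removing one library at a time left a median of at least 1.22, which argues against 1 deviating library as the whole source. Lower cellular levels of several transition metals are a candidate explanation: the exporter genes copB, czcD, yeaB and ydfM had a median of -0.86, with 3 of the 4 past the threshold, although the importer genes mntA, mntB, mntC, mntD and mntH, with a median of 2.62, had 0 of 5 past it by edgeR (5 at an unadjusted p below 0.05, and 5 by DESeq2). For zinc the uptake genes gave little, with znuA at 0.25 and znuB (0.04), znuC (-0.09) and zosA (-0.02) near 0. The zinc list genes folEB, rpsNB and rpmEB were higher only when adjusted over the list alone. A later growth stage of the supplemented cultures stays open, since ribosomal protein genes had a median of -0.0096 with a lower quartile of -0.11, which sets no bound on small differences in growth. No metal content was measured in these data, so the first of these is a hypothesis found and tested on the same libraries.

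PBSX prophage genes rose by a median of 1.74. SOS induction across the culture would raise recA, lexA, dinB, uvrA and uvrB, whose median was -0.0204 and of which lexA and dinB fell. The SOS genes yneB and yneA, however, were at 0.42 and 0.42 without passing (edgeR adjusted p = 0.0924 and 0.15). The SOS list member uvrX, also without passing, was at 0.72 (edgeR adjusted p = 0.109). It lies within the prophage SPβ and had only 1.14 ± 0.21 and 1.89 ± 0.30 CPM without and with MgCl2. Phage DNA carried into the libraries, if it added evenly along the prophage, would raise all its genes alike per kb. The increase in CPM per kb of coding length instead differed 15.8-fold between the 90th and 10th percentile of 29 genes. That argues against evenly added DNA as the whole source. A part from such DNA, or DNA added unevenly, stays open. Induction in a small share of the cells may still be the source and was not tested.

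The dlt operon and the genes sigX, rsiX, abh, bcrC and pbpE fell. Over 117 values under all alternatives the highest log2 change of 9 such genes was -0.54, but the other scalings moved the median of all genes only from 0.0078 to -0.0016, so an error in scaling stays open and the fall is one relative to other genes. A general fall of cell envelope transcripts by equal amounts would lower the peptidoglycan precursor genes as far, but their median was -0.0799 with a lower quartile of -0.14, against -0.41 for the envelope stress list. A smaller general fall stays open, since the precursor list also passed camera as lower (adjusted p = 0.0199, and 0.286 with an estimated correlation). The gene bcrC is also a member of the precursor list. A response of these genes to magnesium itself may account for the pattern, and so might one to the added chloride or osmolarity, which the design does not separate.

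The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share below 0.05. Changed genes numbered 285 in the real split and at most 0 in any other by edgeR, and 1 of the 10 splits reached the real count, as did 1 for the 154 higher genes, 1 for the 131 lower genes and 1 for the 76 genes changed at least 2-fold (highest other 0 each). Every other split puts supplemented and unsupplemented libraries together in both groups. Any MgCl2 effect then widens the spread within groups and lowers the count, so these counts cannot show what chance alone would give. For gene lists past the threshold, 2 of the 10 splits reached the real 12, the highest other being 12. Each of the 12 lists passed camera in at least 1 other split, and 5 had a lower adjusted p in another split than in the real one: flagella (1.56e-08 against 1.18e-05), SigB (6.2e-12 against 7.06e-12), heat shock (0.00215 against 0.0208), osmotic and potassium response (0.00705 against 0.0215) and elongation (0.0107 against 0.0208). The other splits mix the conditions unevenly and keep part of the MgCl2 contrast, so a responding list can pass in them. A pass of such a list is therefore not a false call in itself. Lists with no call in the real split passed in other splits as well, such as purine synthesis in 6 (lowest camera adjusted p = 3.49e-12, against 0.864). Camera with the preset correlation may therefore pass lists that do not respond to MgCl2.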

How the results depend on the processing

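The tests in this part were planned before the data were examined, except the grouping of named genes by calls kept, which was chosen after. Of 123 named genes 68 passed the threshold. All 68 kept their sign under every alternative that tested them, 29 kept their call in all of those, and 22 lost it only when 1 library was left out. The stricter filter did not test named genes at a few CPM, such as fbpB, xkdJ, czcD and yxzC. Over 1585 alternative values of the 123 named genes 1338 were on the same side of the threshold, 165 lost a call, 82 gained one and no call reversed. Among genes not past it, lytE (-0.11 to 0.05) and mreBH (-0.13 to 0.10) took both signs. The 285 changed genes became 513 with DESeq2 (303 higher, 210 lower), of which 282 were among the 285. The 76 genes changed at least 2-fold became 159 with DESeq2, 44 with the stricter filter, which tests fewer genes, and 122 without robust dispersion. With a replicate block 296 genes changed (136 higher and 160 lower), 56 by at least 2-fold, and 221 of the 285 kept their call; libraries of the same number did not deviate together (correlations of -0.18, 0.08 and 0.01). With 1 library left out the count ran from 89 (without control 2) to 377 (without control 3), higher genes from 46 to 169, lower genes from 43 to 208, genes changed at least 2-fold from 34 to 86 and lists past the threshold from 9 to 13. The 12 lists became 0 with an estimated correlation. Apart from the smaller sets of genes or libraries, the cause was not tested. Depth of 16.08 M to 21.08 M reads in genes leaves genes of a few CPM, PBSX among them, with the fewest counts, and the stricter filter tested 12 PBSX genes and called 10.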

Other observations

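The genes in this part were chosen after their values were seen. Outside the fixed list, further genes of siderophore and iron uptake rose with MgCl2. The siderophore-binding gene yfmC rose by 0.94 ± 0.08, its neighbours yfmD, yfmE and yfmF with it (run mean 0.53 over 4 genes), and the yclNOPQ operon for petrobactin uptake by a run mean of 0.61. The gene btr, for the activator of the feu operon, rose by 0.70.

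Of 193 genes of the prophage SPβ 109 were tested. Of these 13 rose, by 0.79 to 3.21, and 8 fell, with a median of 0.09 and 68 genes above 0. The run yonD to yonA had a mean of 1.86 over 4 genes and yomV to youA 2.26 over 3 genes, at low levels.

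Other runs of neighbouring genes fell together. The run yxzC to wapA had a mean of -1.14 over 4 genes and yxiK to yxiH -0.85 over 5, while yqfB, yqfA (floA, a flotillin) and yqeZ had a mean of -0.48 and the lactate utilization genes lutA, lutB and lutC with yvbX -0.34. The glycine cleavage genes gcvT, gcvPA and gcvPB rose by a mean of 0.28. In all, 25 runs of at least 3 neighbouring changed genes held 102 of the 285 changed genes.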
